A study of Mus musculus with 6 samples.

How the data were processed

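Expression was measured on 6 single-colour Affymetrix Mouse Gene ST arrays, each hybridised with amplified, biotin-labelled cDNA from the total RNA of sorted mouse hematopoietic cells. Of these arrays, 3 are labelled EVI1 and 3 are labelled EGFP. The values the authors deposited are log2 intensities, 1 per probe set and array. They were made by RMA, which corrects background, normalises the arrays to common quantiles and summarises the probes of a probe set, per the submitters' processing notes; the RMA version and the background set are not given in the sources used here. Medians of the 6 arrays lay between 7.24 and 7.31. Arrays have no read depth, and their number limits the precision of the values. No detection calls were used here, so signal could not be set against a background measured on the array. Because RMA brings the arrays close to a common distribution, a change of the total RNA per cell would not appear in these values.

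The deposited values were used without rescaling. Of 34760 probe sets, 21640 carried exactly 1 gene symbol in the probe annotation, 1321 carried several and 11799 were unnamed here. Each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 19937 genes, 954 of them with more than 1 probe set. No filter on dim probe sets was applied. Identifiers of 19855 genes were found in the RefSeq gene table, and no symbol was updated. Genome coordinates were not used.

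Arrays were grouped by the construct in their labels. Each gene was compared between the 3 EVI1 and the 3 EGFP arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust estimation), a two-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was said to rise or fall at an adjusted p under 0.05. Log2 fold changes are EVI1 minus EGFP. The standard errors (SE) come from the same fit, and SD is the spread of the 3 arrays of a group. For Mecom an exact two-sided permutation test was added, for which 3 arrays against 3 allow no p under 0.1. The labels do not say whether replicates are separate animals, cultures or transductions, so the p-values of single genes measure the spread between these arrays only.

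The 24 gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The lists were taken from general knowledge and cover stem cells, genes linked to EVI1 in earlier work, neutrophils and granules, monocytes and macrophages, erythroid cells, megakaryocytes and platelets, mast cells and basophils, eosinophils, lymphoid cells, dendritic cells and antigen presentation, stromal and endothelial cells, DNA replication and S phase, G2/M and mitosis, cell cycle inhibitors, p53 targets, the TGF-beta response, AP-1 and immediate early genes, the interferon response, ribosome biogenesis and Myc targets, the unfolded protein and integrated stress response, cholesterol synthesis, apoptosis regulators, cytokine receptors and their signalling feedback, and cell adhesion and homing. They held 630 different symbols, of which 578 were measured (6 of them under another symbol) and 52 were not measured here. Mecom was left out of every list. Members were counted at an adjusted p under 0.05 over all genes and again adjusted over the list alone. Each list was tested against the other genes with camera from limma at its preset correlation of 0.01, and p-values were adjusted over the 24 lists. At that setting camera takes its degrees of freedom from the number of genes, so very small p-values do not measure the spread between arrays. The test was repeated with a correlation estimated from the residuals, on ranks, and with fry, which asks only whether the members of a list move, on balance, one way. With an estimated correlation camera takes its degrees of freedom from the residuals of these 6 arrays instead. That weakens the test, so a call lost there can reflect few arrays as well as correlated members.

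The named genes were Mecom, the 12 largest rises and the 12 largest falls among changed genes whose groups did not overlap, and in each list the up to 4 members with the smallest p. Unnamed predicted genes, olfactory receptors and small RNA genes were left out of the first 2 sets of 12. Other members were named after their values had been seen, where they make up a small count or carry a contrast within a list; these are Ifit1, Ifitm3, Mx2, Ifi35, Myc, Cdkn1b, Rbl1, S100a8, S100a9, Cd177, Sptb, Cpox, Lyz2, Chil3, Padi4, Ly6g, Mmp9, Cebpd, Anxa1, Clec4n, Ccr2, Blvrb, Epor, Gata1, Klf1, Pf4, Ppbp, Cpa3, Slc18a2, Gata2, Hoxa9, Kit, Meis1, Spi1, Adgrg1, Angpt1, Gfi1b, Dnajb9, Trib3, Slc7a11, Bid, Aen, Id2, Ltbp1, Dusp6, Nr4a3, Etv5, Pim1, Cd93, Itgb4, Cybb, Cd68, Psap, Mpeg1, Mrc1, Tlr4, Csf1r and Cd14.

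Replicate numbers were checked for pairing. The deviations of same-numbered EVI1 and EGFP arrays from their group means correlated across genes at r = 0.491, 0.269 and 0.197 for replicates 1, 2 and 3, so a fit with the replicate number as a block was run beside the unpaired fit, and its value is given where it changes the call of a list or of a gene named by rule, and for the lists whose member counts it moved most. Other alternatives were a further quantile normalisation, centring each array on its median, filters at the 25th and the 50th percentile of mean level, eBayes with trend and robust estimation, array weights, the mean over the probe sets of a gene, every probe set including unnamed ones, an adjusted p under 0.01, and leaving out each array in turn. After the data were seen, a filter at the 95th percentile of 1027 olfactory receptor genes was added, these being genes that blood cells are not known to use; where one group's mean lies under that level, the size of the fold change is uncertain. The procedure was tested on simulated data of the same size with 200 of 19937 genes changed. It found 70% of genes shifted by 1 on the log2 scale and 95% of those shifted by 2, 1.79% of its calls were unchanged genes, and it called 0 genes when no group effect was simulated. A simulated list of 30 genes shifted by 1 was called by camera with the preset and with the estimated correlation. The simulated genes varied independently of each other, while the estimated correlation was 0.757 in the interferon list. These checks therefore do not cover correlated genes, paired arrays or a share of changed genes as large as in the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

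Left out of the gene test were the probe sets with several symbols and those unnamed here.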

Results

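The 6 arrays measured mouse hematopoietic cells of the C57BL6 strain depleted of cells that carry mature lineage markers (Lin-), a fraction rich in stem and progenitor cells. The cells came from Rosa26rtTA mice, whose ubiquitous reverse tetracycline transactivator switches on tetracycline-responsive promoters when doxycycline is present. They were grown without serum in stem cell factor (50 ng/ml), interleukin 3 (20 ng/ml), Flt3 ligand (50 ng/ml) and interleukin 11 (50 ng/ml). A lentiviral vector was added 24 h after isolation, and doxycycline (1 µg/ml) followed 24 h later. The vector carried either EVI1, a zinc finger transcription factor made from the Mecom locus and overexpressed in some myeloid leukemias, together with the green fluorescent protein EGFP, or EGFP alone. EGFP-positive cells were sorted and their RNA was taken 20 h after doxycycline in one description and 24 h after it in another. There were 3 arrays for each construct. The question was which transcripts differ when EVI1 is expressed in such cells for about a day.

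Mecom, the gene whose product was to be overexpressed, was not higher in the arrays labelled EVI1. Its brighter probe set averaged 6.92 ± 0.57 (SD, n = 3) in the EGFP arrays and 6.32 ± 0.16 (SD, n = 3) in the EVI1 arrays, with single values of 6.39, 7.53 and 6.86 against 6.29, 6.18 and 6.49. The log2 difference was -0.60 ± 0.26 (SE), which did not pass the test (limma adjusted p = 0.166; exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). Without EGFP replicate 1 the difference was -0.87 with an adjusted p of 0.0306, and without EGFP replicate 2 it was -0.30 with an adjusted p of 0.279. The other Mecom probe set averaged 6.58 ± 0.12 (SD) and 6.35 ± 0.05 (SD), a difference of -0.23 with an exact permutation p of 0.1. All these means lay under the 95th percentile of olfactory receptor genes, 6.95 in the EGFP arrays and 6.99 in the EVI1 arrays. Whether the probes read the transduced sequence is not known here, so the groups are named by their labels throughout, and each direction is that of the labels.

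The groups differed in a large part of the transcriptome, with the cell cycle and ribosome biogenesis lists lower and the interferon list higher in the arrays labelled EVI1 by camera at its preset correlation. These list calls were lost with an estimated correlation, where the lowest adjusted p was 0.199. Of 19937 genes, 3638 (18.2%) changed, of which 1807 rose and 1831 fell. Changes of at least 2-fold were found for 1177 genes, 573 up and 604 down. Large rises were more numerous than large falls, at 131 against 55 genes beyond 4-fold and 39 against 6 beyond 8-fold. With a replicate block 4361 genes changed, 2172 up and 2189 down, and 3585 genes were called in the same direction by both fits. All EVI1 values lay on one side of all EGFP values for 6504 genes (32.6%), where chance gives 10%. The first principal component held 67.3% of the variance and parted the groups, and arrays correlated across genes at r = 0.976 to 0.990 within groups and 0.942 to 0.959 between them. Without EVI1 replicate 3 the count of changed genes was 2289, with 1179 genes up and 1110 down. EGFP replicate 2 stood somewhat apart, with the lowest mean correlation to its own group (0.979). Its array weight, lower where an array is noisier, was 0.452, with 0.874 to 1.55 for the others. Without it 4098 genes changed.

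The steepest rises included the cathepsins Ctsj and Ctsr and the innate defence genes Rsad2, Il18 and Cfb. Ctsj, a cathepsin of the placental gene cluster, went from 5.85 ± 0.11 to 11.51 ± 0.34 (SD, n = 3 arrays each), a 50.5-fold rise (log2 5.66 ± 0.17 SE, adjusted p = 4.23e-06). Its neighbour Ctsr rose by 4.79 ± 0.18. Rsad2, which encodes the antiviral protein viperin, went from 7.15 ± 0.17 to 12.13 ± 0.18, a 31.6-fold rise (4.98 ± 0.14, adjusted p = 4.23e-06). Il18, an inflammatory cytokine, rose by 4.45 ± 0.34, Cfb, complement factor B, by 4.13 ± 0.16, Chil1, a chitinase-like protein, by 4.46 ± 0.34, and Fcer2a, the low-affinity IgE receptor, by 4.08 ± 0.20. Spic, a transcription factor needed for red pulp macrophages, rose 24.0-fold (4.58 ± 0.42). Ldhb, a lactate dehydrogenase subunit, rose by 4.66 ± 0.15, the amino acid transporter Slc6a20a by 4.40 ± 0.14, Pdzk1ip1, a membrane protein enriched in stem cells, by 4.24 ± 0.14, and Enkur by 4.17 ± 0.27. For Ctsj, Ctsr, Ldhb, Il18, Enkur and Fcer2a the EGFP mean lay under the 95th percentile of olfactory receptor genes, and Ctsj and Ctsr are close paralogs, for which hybridisation to each other's probes was not tested.

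The steepest falls included the neutrophil genes Mmp8 and Ngp, the mast cell enzyme gene Tph1 and the cytotoxic granule gene Nkg7. Sh2d1b1, an adaptor of natural killer cell signalling, went from 9.62 ± 0.58 to 6.15 ± 0.56 (SD, n = 3 arrays each), an 11.1-fold fall (log2 -3.47 ± 0.34 SE, adjusted p = 0.000416). Mmp8, the neutrophil collagenase, went from 11.12 ± 0.60 to 7.67 ± 1.37, a 10.9-fold fall (-3.45 ± 0.61, adjusted p = 0.00595), and Ngp, a neutrophil granule protein, fell by 2.87 ± 0.46. Nkg7, a cytotoxic granule protein (-3.06 ± 0.16), Tph1, the tryptophan hydroxylase of mast cells (-3.20 ± 0.29), and the T cell adaptor Tespa1 (-2.90 ± 0.17) fell. Falls were also found for Cd33, a sialic acid-binding lectin of myeloid cells (-3.07 ± 0.28), the Fc receptor Fcgr3 (-2.88 ± 0.24), Trem3 (-2.75 ± 0.17), Gpr65 (-2.96 ± 0.47) and Gpr141 (-2.90 ± 0.32). The endothelial lipase Lipg fell by 2.73 ± 0.23. For Sh2d1b1, Tph1, Gpr141 and Tespa1 the EVI1 mean lay under the 95th percentile of olfactory receptor genes.

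**Figure D1:**
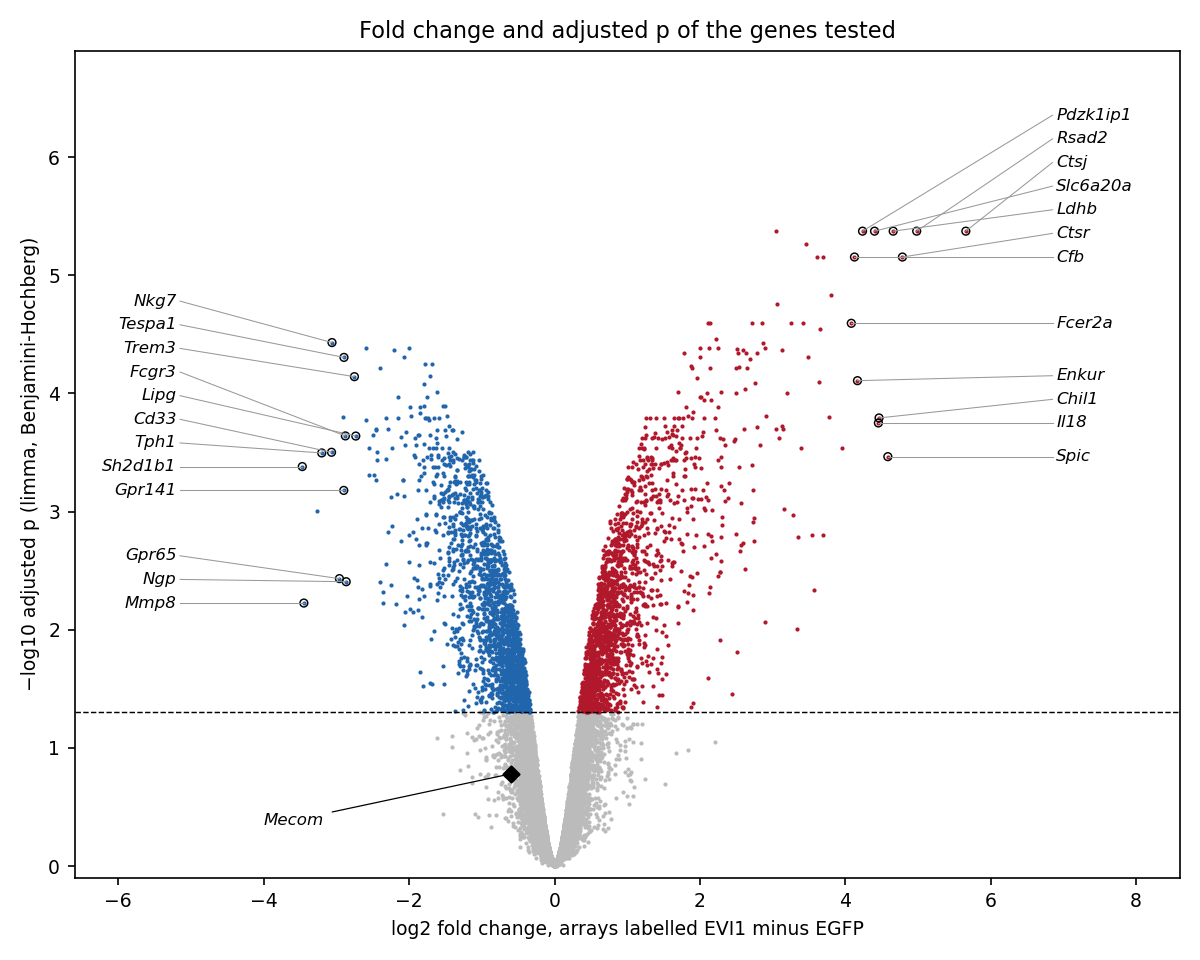
Each point is 1 of the 19937 genes tested, with the log2 fold change (arrays labelled EVI1 minus EGFP, 3 each) on the horizontal axis and the negative log10 of the limma adjusted p on the vertical axis; red points rose, blue points fell, gray points did not pass and the dashed line marks an adjusted p of 0.05. The 12 largest rises and the 12 largest falls of the named set are circled, from Ctsj at 5.66 to Sh2d1b1 at -3.47, and Mecom (diamond) lies at -0.60 under the line.

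Genes that drive the cell cycle were lower in the arrays labelled EVI1. Of 44 measured genes of DNA replication and S phase 37 fell, none rose and 7 did not pass, and 40 fell when adjusted over the list alone; the median log2 fold change was -1.37. Examples are Mcm4, a subunit of the replicative helicase (-1.62 ± 0.11, log2 fold change ± SE here and in what follows, n = 3 arrays per group), Exo1, a DNA repair exonuclease (-1.85 ± 0.13), Brip1, a repair helicase (-1.78 ± 0.11) and Dtl, which directs replication factors to degradation (-1.79 ± 0.13). The list was lower by camera (adjusted p = 5.96e-29), a call lost at adjusted p = 0.199 with an estimated correlation. Of 49 genes of G2/M and mitosis 43 fell, none rose and 6 did not pass, with 46 lower adjusted over the list alone and a median of -0.99. Cyclin A2 (Ccna2, -1.22 ± 0.11), the topoisomerase Top2a (-1.12 ± 0.12), the mitotic kinase Ttk (-1.45 ± 0.15) and Cks1b, a cofactor of cyclin-dependent kinases (-1.19 ± 0.12), were among those that fell. Camera gave an adjusted p of 8.89e-27, and adjusted p = 0.308 with an estimated correlation. Among 23 cell cycle inhibitors 10 rose, 1 fell (Rbl1, a pocket protein, -0.59) and 12 did not pass, with 12 up and 2 down adjusted over the list alone and a median of 0.57. The inhibitor Cdkn1c (p57) rose by 1.31 ± 0.10, Cdkn1b (p27) by 1.12 ± 0.21, the antiproliferative gene Tob1 by 1.43 ± 0.12, Txnip, which binds thioredoxin, by 1.44 ± 0.17 and Trp53inp1, a p53-induced gene, by 1.17 ± 0.15. Camera gave an adjusted p of 0.000709, and adjusted p = 0.308 with an estimated correlation. Without EVI1 replicate 2 the median of the inhibitors was 0.31.

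The ribosome biogenesis, cholesterol synthesis and stress response lists were lower as well. Of 33 genes of ribosome biogenesis and Myc targets 24 fell, none rose and 9 did not pass, and 30 were lower adjusted over the list alone, with a median of -0.99. Myc itself, a transcription factor of cell growth, fell by 2.00 ± 0.30. The nucleolar protein Nop56 (-1.78 ± 0.13), Utp20, which processes ribosomal RNA (-1.39 ± 0.12), Polr1a, the large subunit of RNA polymerase I (-1.40 ± 0.13), and spermidine synthase (Srm, -2.44 ± 0.23) fell too. The camera adjusted p was 5.59e-19, and adjusted p = 0.287 with an estimated correlation. Of 18 genes of cholesterol synthesis 7 fell, none rose and 11 did not pass, with 9 lower adjusted over the list alone, 11 with a replicate block and a median of -0.39. Lanosterol synthase (Lss, -1.18 ± 0.20) and the sterol dehydrogenase Nsdhl (-0.58 ± 0.11) fell. The camera adjusted p was 0.000131, and adjusted p = 0.308 with an estimated correlation. In the unfolded protein and integrated stress response 10 of 24 genes fell, 3 rose and 11 did not pass, with 13 down and 4 up adjusted over the list alone and a median of -0.36. The stress transcription factor Atf4 (-0.86 ± 0.16), its serine synthesis target Psat1 (-1.40 ± 0.23), and Sdf2l1 (-0.98 ± 0.13) and Manf (-0.83 ± 0.14) of the endoplasmic reticulum fell. The 3 that rose were the chaperone Dnajb9 (0.77), the pseudokinase Trib3 (0.38) and the cystine transporter Slc7a11 (1.20). The camera adjusted p was 0.00400, and adjusted p = 0.308 with an estimated correlation.

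The interferon response was the list with the highest median. Of 27 measured genes 23 rose, none fell and 4 did not pass, with 24 higher adjusted over the list alone and a median of 1.54. Rsad2 led the list (4.98 ± 0.14). Ifit1, which binds viral RNA, rose by 3.69 ± 0.49, Oasl2 of the oligoadenylate synthetase family by 2.73 ± 0.30, the RNA sensor Ddx58 (RIG-I) by 1.95 ± 0.17 and Trim30a by 1.45 ± 0.17. Members that did not pass included Ifitm3 (0.27 ± 0.10), Mx2 (1.25 ± 0.55, with an EGFP mean under the 95th percentile of olfactory receptor genes) and Ifi35 (0.35 ± 0.17). Array means of the list were 8.63, 8.23 and 8.52 in the EGFP arrays and 10.7, 9.64 and 10.8 in the EVI1 arrays. The camera adjusted p was 5.50e-17, and adjusted p = 0.308 with an estimated correlation. The labels give no vector dose for either group.

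Genes of neutrophils and their granules went both ways. Of 28 measured genes 10 fell, 5 rose and 13 did not pass, with 11 down and 6 up adjusted over the list alone, 14 down and 6 up with a replicate block, and a median of -0.33. Those that fell included Mmp8 (-3.45 ± 0.61) and Ngp (-2.87 ± 0.46), myeloperoxidase (Mpo, -2.55 ± 0.26), neutrophil elastase (Elane, -2.29 ± 0.18), cathepsin G (Ctsg, -2.55 ± 0.23), Ms4a3 (-2.32 ± 0.22) and the surface protein Cd177 (-0.80 ± 0.22). The 5 that rose were the histone-modifying enzyme Padi4 (1.25 ± 0.14), the surface marker Ly6g (2.59 ± 0.36), gelatinase B (Mmp9, 1.92 ± 0.27), the transcription factor Cebpd (0.87 ± 0.24) and annexin A1 (Anxa1, 0.72 ± 0.20). The EGFP means of Ly6g and Mmp9 and the EVI1 mean of Ly86 lay under the 95th percentile of olfactory receptor genes. The bright genes S100a8 (-0.19 ± 0.32), Lyz2 (0.12 ± 0.14) and Chil3 (-0.26 ± 0.28) did not pass, nor did S100a9 (-0.44 ± 0.31), which passed with a replicate block (0.0298). The list as a whole was not called (camera adjusted p = 0.0538), but passed with a replicate block (0.0139), after a further quantile normalisation (0.0332) and without EGFP replicate 2 (0.0376), EGFP replicate 3 (0.0165), EVI1 replicate 1 (0.0105) or EVI1 replicate 2 (0.0368). It was not called at adjusted p = 0.509 with an estimated correlation, nor at 0.431 with both that and the block, and its median was -0.14 without EGFP replicate 1, -0.18 without EVI1 replicate 3 and -0.50 without EVI1 replicate 1. Of 25 monocyte and macrophage genes 7 rose, 6 fell and 12 did not pass, with 7 up and 8 down adjusted over the list alone, 7 up and 9 down with a replicate block, and a median of -0.11 (camera adjusted p = 0.572). Coagulation factor XIII (F13a1, -1.75 ± 0.16), the Toll-like receptor accessory protein Ly86 (-1.65 ± 0.21) and the chemokine receptor Ccr2 (-2.36) fell, while cathepsin S (Ctss, 1.00 ± 0.14) and the lectin Clec4n (2.14) rose. Without EGFP replicate 1 that median was 0.027.

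**Figure D2:**
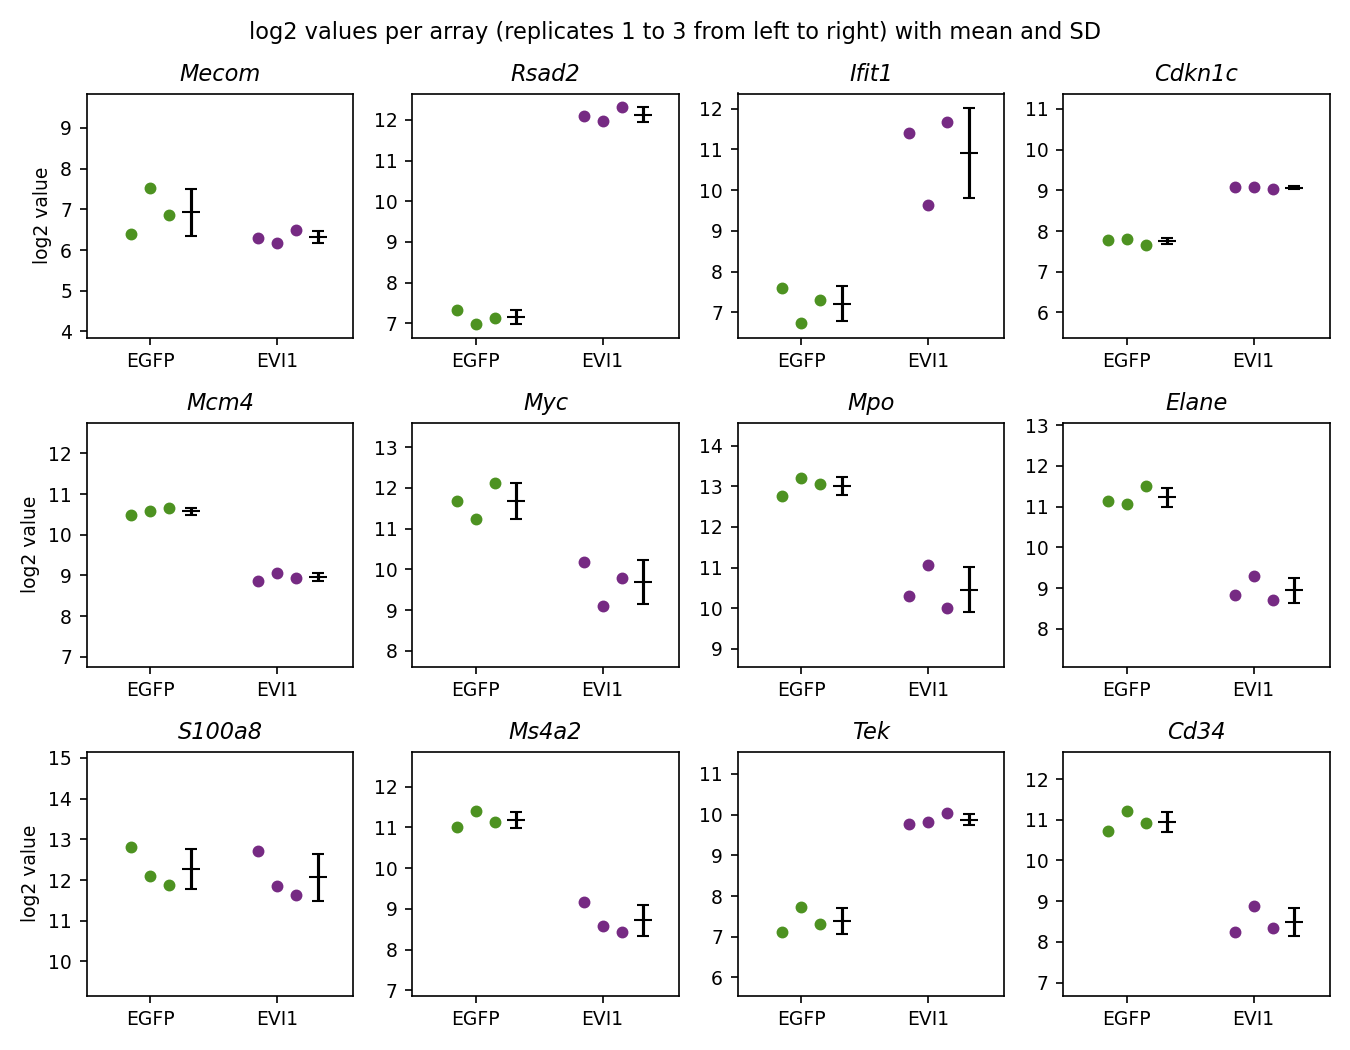
Log2 values of 12 genes in each array (points, replicates 1 to 3 from left to right; green EGFP, purple EVI1) with the group mean and SD (bars), each panel spanning the same number of log2 units. Groups are apart for Rsad2 and Ifit1 (higher in the arrays labelled EVI1) and for Mcm4, Myc, Mpo and Elane (lower), while the ranges of S100a8 overlap and Mecom averages 6.92 in EGFP and 6.32 in EVI1 arrays.

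Mast cell and basophil genes were lower in the arrays labelled EVI1. Of 25 measured genes 13 fell, 1 rose (the monoamine transporter Slc18a2, 0.68) and 11 did not pass, with 13 down and 2 up adjusted over the list alone and a median of -0.49 (-0.78 and -1.24 without probe sets under the 25th percentile and the median of mean level). The IgE receptor subunit Ms4a2 (-2.46 ± 0.20), histidine decarboxylase (Hdc, -2.29 ± 0.30), the leukotriene enzyme Alox5 (-1.62 ± 0.14) and mast cell carboxypeptidase (Cpa3, -1.27) fell. Camera gave an adjusted p of 7.36e-06, and adjusted p = 0.308 with an estimated correlation. None of the 7 eosinophil genes rose or fell by limma, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05; the list median was -0.51 (camera adjusted p = 0.0894, 0.0259 with a replicate block and 0.0364 without EVI1 replicate 1). That median was -0.83 without probe sets under the median of mean level. The eosinophil list had adjusted p = 0.385 with an estimated correlation, and 0.401 with the block added. Eosinophil peroxidase (Epx) differed by -0.72 ± 0.25 and the granule protein Prg2 by -0.83 ± 0.32, and both passed with a replicate block (0.00523 and 0.0214), as did Prg3 (0.0255). Without EVI1 replicate 3 Epx differed by -0.45 and Prg2 by -0.48, and without EGFP replicate 1 Prg3 differed by -0.25. The EVI1 mean of Prg3 lay under the 95th percentile of olfactory receptor genes, so its difference is uncertain in size.

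Erythroid genes were slightly higher, with 6 of 26 up, none down and 20 not passing, 8 up adjusted over the list alone and a median of 0.21; with a replicate block 8 were up and 2 down, Cpox (-0.49, adjusted p = 0.0319) and Sptb (-0.43, 0.0475). The membrane skeleton protein Tmod1 rose by 1.52 ± 0.13, the anion exchanger Slc4a1 (band 3) by 1.45 ± 0.21, Trim10 by 0.93 ± 0.14, the transcription factor Nfe2 by 0.90 ± 0.13, biliverdin reductase B (Blvrb) by 1.04 and the erythropoietin receptor (Epor) by 0.46. Tmod1 has 2 probe sets, and its rise was between 0.83 and 1.53 in the alternatives that kept all 6 arrays. The erythroid regulators Gata1 (0.22) and Klf1 (0.092) did not pass, and the EGFP mean of Trim10 lay under the 95th percentile of olfactory receptor genes. Camera called the erythroid list at an adjusted p of 0.0293, and the call was lost at adjusted p = 0.330 with an estimated correlation, at 0.0533 on ranks, at 0.0590 and 0.0768 with the filters on dim probe sets, and at 0.0753 without EGFP replicate 1. Of 22 megakaryocyte and platelet genes 8 fell, 4 rose and 10 did not pass, with 10 down and 6 up adjusted over the list alone and a median of -0.29. The thrombin receptor F2rl2 (-2.32 ± 0.17), pleckstrin (Plek, -1.44 ± 0.15), the adaptor Lat (-1.39 ± 0.19) and platelet factor 4 (Pf4, -1.41) fell, and integrin beta 3 (Itgb3, 1.34 ± 0.15) and the platelet chemokine Ppbp (1.37) rose. Camera did not call it (adjusted p = 0.0728), except without EGFP replicate 3 (0.0470), and had adjusted p = 0.385 with an estimated correlation.

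Stem cell genes split in direction. Of 39 measured genes 6 rose, 7 fell and 26 did not pass, with 8 in each direction adjusted over the list alone and a median of 0.079 (camera adjusted p = 0.302; a median of 0.042 without EGFP replicate 1). Pdzk1ip1 (4.24 ± 0.14), the angiopoietin receptor Tek (2.49 ± 0.17) and Ctnnal1 (1.98 ± 0.18) rose. The progenitor antigen Cd34 (-2.45 ± 0.20), the stem cell factor receptor Kit (-0.61) and the homeobox gene Meis1 (-0.66) fell. Gata2 (-0.076) and Hoxa9 (0.023), transcription factors of early progenitors, did not pass. Of 26 genes linked to EVI1 in earlier work 4 rose, 5 fell and 17 did not pass, with 5 in each direction adjusted over the list alone and a median of -0.082 (camera adjusted p = 0.549; medians of -0.077 to -0.0050 leaving out 1 array, the last without EVI1 replicate 2). This list sets no direction for its members, so opposite changes cancel in camera and in the median. The form of fry that asks for change in either direction gave an unadjusted p of 2.84e-06. It gave 6.63e-06 for the monocyte and macrophage list, so such a value is not particular to genes linked to EVI1. The tetraspanin Cd82 (1.11 ± 0.16), the myeloid transcription factor Spi1 (0.73), the adhesion receptor Adgrg1 (0.83) and Epor (0.46) rose. Those that fell were Mpo, the plasminogen activator inhibitor Serpinb2 (-1.79 ± 0.15), the transcription factors Runx1 (-0.81 ± 0.13) and Gfi1b (-0.84), and angiopoietin 1 (Angpt1, -0.88). The EVI1 mean of Serpinb2 lay under the 95th percentile of olfactory receptor genes.

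Of 23 lymphoid genes 5 fell, 4 rose and 14 did not pass, with 5 in each direction adjusted over the list alone and a median of -0.023 (camera adjusted p = 0.685; medians of -0.085 to 0.025 leaving out 1 array). The interleukin 7 receptor (Il7r, -2.46 ± 0.25), the interleukin 2 receptor alpha chain (Il2ra, -0.94 ± 0.10) and the receptor tyrosine kinase Flt3 (-1.52 ± 0.23) fell, and the B cell receptor component Cd79b (1.22 ± 0.20) rose. Of 19 genes of dendritic cells and antigen presentation 6 fell, 1 rose and 12 did not pass, with 6 down and 2 up adjusted over the list alone and a median of -0.27. The integrin Itgax fell by 1.19 ± 0.17, and the gene that rose, Bst2 (0.95 ± 0.19), is also a member of the interferon list. Camera gave an adjusted p of 0.0504 for the dendritic list, 0.0294 with a replicate block, 0.0332 after a further quantile normalisation and 0.0345 on ranks, and between 0.0271 and 0.0353 without EGFP replicate 1, EGFP replicate 3 or EVI1 replicate 2. The dendritic list had adjusted p = 0.385 with an estimated correlation, and 0.458 with the block added. Of 17 stromal and endothelial genes 2 rose, 1 fell and 14 did not pass, with 2 up and 2 down adjusted over the list alone and a median of 0.031 (camera adjusted p = 0.843; -0.011 without EGFP replicate 1, and the rank test put its direction down). The endothelial genes Cdh5 (VE-cadherin, 2.61 ± 0.17) and Kdr (a VEGF receptor, 1.54 ± 0.32) rose. The EGFP means of Cdh5 and Kdr and the EVI1 means of Il7r, Il2ra and Itgax lay under the 95th percentile of olfactory receptor genes.

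Among apoptosis regulators 7 of 21 rose, 2 fell and 12 did not pass, with 8 up and 2 down adjusted over the list alone and a median of 0.22. Risers encode proteins on both sides of cell death, with the death receptor Fas (2.28 ± 0.19) beside the survival genes Mcl1 (1.05 ± 0.13) and Cflar (0.97 ± 0.15), and the 2 that fell were the survival gene Bcl2 (-1.67 ± 0.15) and the death gene Bid (-0.78). Cflar has 3 probe sets, and its rise was between 0.54 and 1.01 in the alternatives that kept all 6 arrays. Camera called the apoptosis list at an adjusted p of 0.0154, with adjusted p = 0.308 with an estimated correlation and 0.0687 after the filter at the median level; its median was 0.37 without EGFP replicate 2 and 0.33 without EVI1 replicate 1. Of 23 p53 targets 4 rose, 1 fell (Aen, an apoptosis nuclease, -0.47) and 18 did not pass, with 5 up and 1 down adjusted over the list alone and a median of 0.17. Fas and Trp53inp1 were among the p53 targets that rose. The p53 list had a camera adjusted p of 0.0691, 0.0341 with a replicate block, 0.0249 with array weights and 0.0127 without EGFP replicate 2. It had adjusted p = 0.375 with an estimated correlation, and 0.458 with the block added. Of 23 TGF-beta response genes 7 rose, 3 fell and 13 did not pass, with 8 up and 4 down adjusted over the list alone and a median of 0.19 (camera adjusted p = 0.0897). The filter at the median of mean level took the TGF-beta median to 0.38. The integrin Itgav, which activates TGF-beta, rose by 1.67 ± 0.14, its co-receptor Tgfbr3 by 0.94 ± 0.13 and the feedback repressor Skil by 0.74 ± 0.13, while the ligand Tgfb1 (-1.08 ± 0.16), the transcriptional inhibitor Id2 (-1.88) and the TGF-beta binding protein Ltbp1 (-0.34) fell. Of 33 AP-1 and immediate early genes 10 rose, 3 fell and 20 did not pass, with 10 up and 4 down adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.0908; a median of 0.066 without EVI1 replicate 1). The orphan receptors Nr4a2 (2.02 ± 0.20) and Nr4a1 (0.94 ± 0.14), the AP-1 subunit Fosl2 (1.00 ± 0.11) and Ier3 (1.05 ± 0.11) rose, and Dusp6 (-0.83), Nr4a3 (-0.78) and Etv5 (-1.30) fell. The EVI1 means of Nr4a3 and Ltbp1 lay under the 95th percentile of olfactory receptor genes.

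Of 23 cytokine receptors and signalling feedback genes 9 fell, 3 rose and 11 did not pass, with 10 down and 5 up adjusted over the list alone and a median of -0.27 (camera adjusted p = 0.0908; a median of -0.15 without EVI1 replicate 3). Il7r and Flt3 fell as given among the lymphoid genes, and Csf2rb, the beta chain shared by the receptors of interleukin 3, interleukin 5 and GM-CSF, fell by 2.08 ± 0.22. The 3 that rose were the repressor Bcl6 (1.63 ± 0.15), the kinase Pim1 (0.71) and Epor. Of 26 adhesion and homing genes 4 rose, 3 fell and 19 did not pass, with 4 up and 5 down adjusted over the list alone and a median of -0.13 (camera adjusted p = 0.685). That median ran from -0.18 to -0.0049 leaving out 1 array and was 0.032 with the filter at the median of mean level. The integrin chains Itgb7 (1.18 ± 0.13), Itgb3 (1.34 ± 0.15) and Itgb4 (0.78) and Cd82 rose, while both chains of LFA-1, Itgal (-1.54 ± 0.18) and Itgb2 (-1.59 ± 0.20), and Cd93 (-0.97) fell.

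**Figure D3:**
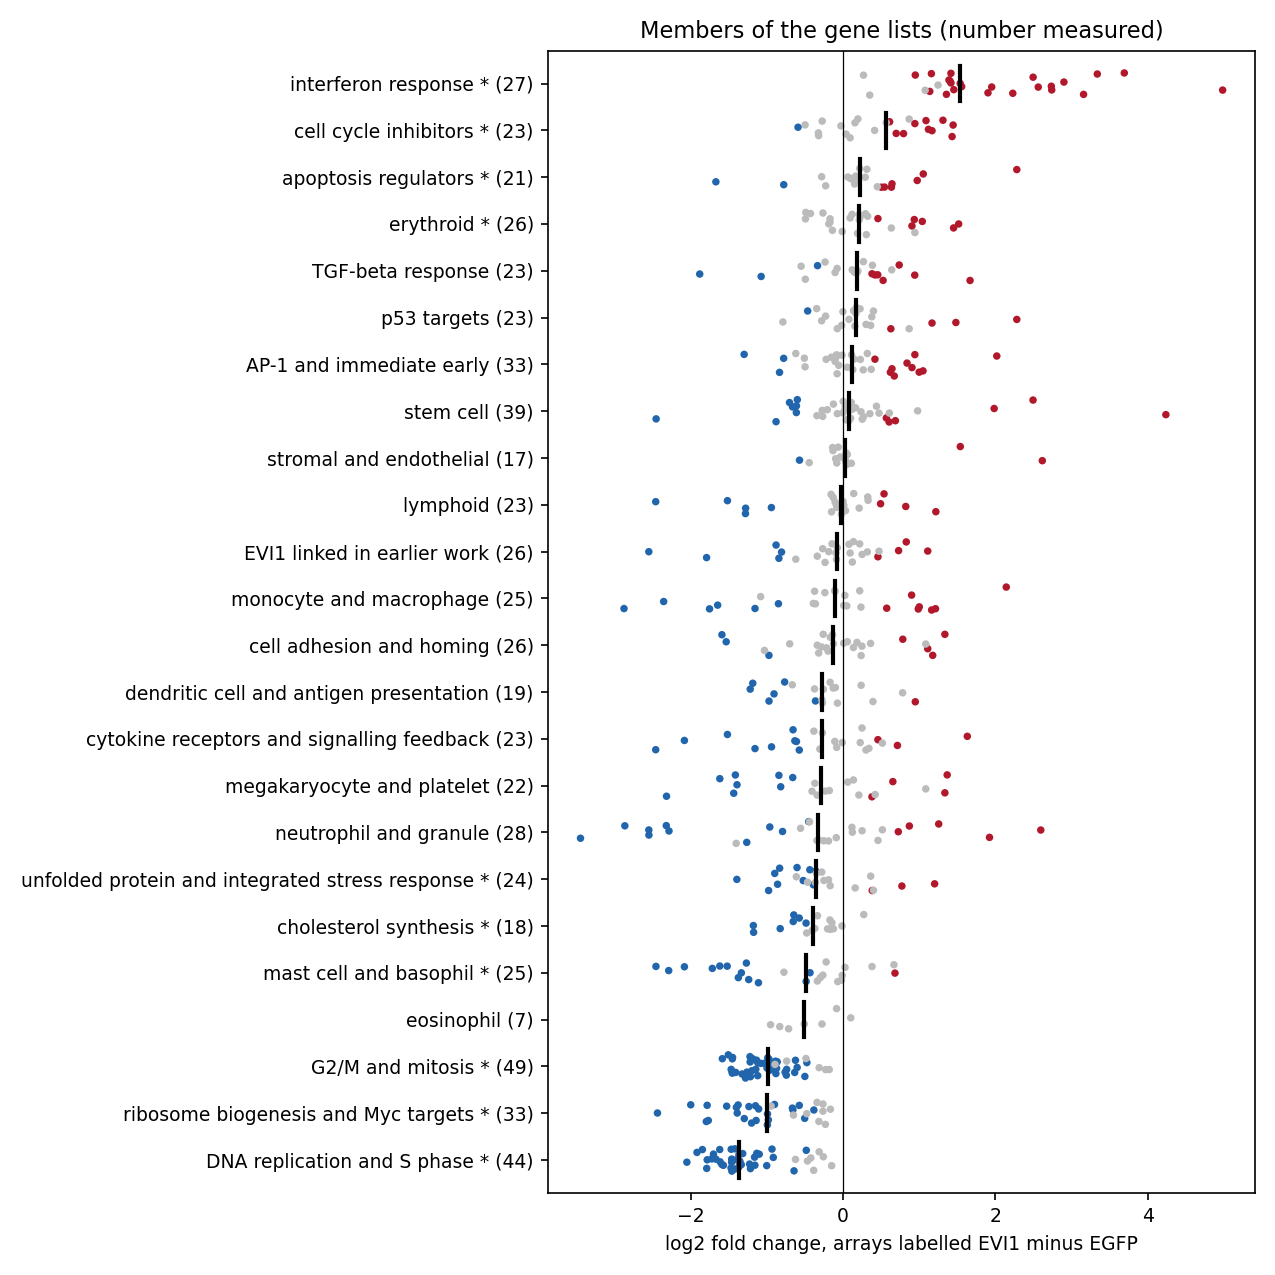
Each point is a measured member of 1 of the 24 gene lists (number measured in brackets), placed at its log2 fold change, arrays labelled EVI1 minus EGFP; red rose, blue fell, gray did not pass, black bars are medians and asterisks mark lists called by camera at the preset correlation. Medians run from 1.54 for the interferon response to -1.37 for DNA replication and S phase.

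In all, camera at the preset correlation called 10 of the 24 lists, 4 higher and 6 lower in the arrays labelled EVI1. With an estimated correlation it called 0, the lowest adjusted p being 0.199, and 3 lists had an unadjusted p under 0.05; fry called 17. At the preset correlation camera also called between 4 and 10 lists under the other divisions of the 6 arrays into 3 and 3. Each of those divisions puts unequal numbers of EVI1 and EGFP arrays on its sides. Lists that differ between the labels can therefore be called there, and these counts are no rate of false calls.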

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

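The comparisons with other divisions of the arrays and the fit over every probe set were planned, as were the gene and list tests whose values are repeated here. The other checks of explanations in this part were chosen after the patterns they address were seen. Of the 10 ways to divide the 6 arrays into 3 and 3, 1 gave as many changed genes as the labels (3638, with 0 as the highest of the others by limma, although 104 to 1323 genes had an unadjusted p under 0.05 there), and likewise 1 gave as many genes changed at least 2-fold (1177, with 0 as the highest of the others). For the number of gene lists called, 2 of the 10 divisions gave 10 lists, namely the labelled one and that of EGFP replicates 1 and 3 with EVI1 replicate 1 against the rest. Among the 4 divisions that part all same-numbered arrays, the highest other values were 0 genes, 0 genes at 2-fold and 7 lists. The 10 divisions are too few for a share under 0.05. Each of the others also mixes the labelled groups, so a difference between the labels adds to the spread within its sides. Their 0 genes are therefore not a measure of what chance gives. Part of such a difference also stays between the sides, so their list counts are no rate of false calls.

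Mecom, the gene meant to be overexpressed, averaged 6.32 in the arrays labelled EVI1 and 6.92 in those labelled EGFP. An exchange of single arrays between the groups is argued against, since the lowest correlation within a group, 0.976, lies above the highest between groups, 0.959. Probes that do not read the transduced sequence may account for it: the EVI1 mean of 6.32 lies under the 95th percentile of olfactory receptor genes (6.99), as such probes would give, but the species and extent of the transduced sequence are not known here. Labels turned round for the whole groups, with probes that read the sequence, would put Mecom well above unexpressed genes in the arrays labelled EGFP. The EGFP mean of 6.92 does not show this, as it also lies under that percentile (6.95), although EGFP replicate 2 read 7.53. If the probes do not read the sequence, Mecom cannot tell which way the labels run. No biological explanation was tested, and a lower level of the cell's own transcript stays open.

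Interferon response genes were higher in every EVI1 array, with list means of 10.7, 9.64 and 10.8 against 8.63, 8.23 and 8.52. More monocytes or macrophages among the sorted cells stay open. Lineage depletion removes mature cells, but culture with cytokines followed it, and maturation there was not measured. The monocyte and macrophage list had a median of -0.11 (SD over members 1.17) against 1.54 for the interferon list, but its members went both ways. Ctss (1.00), Cd68 (1.16), Psap (0.57), Mpeg1 (1.21), Clec4n (2.14), Mrc1 (0.99) and Tlr4 (0.90) rose. Fcgr3 (-2.88), Ccr2 (-2.36), F13a1 (-1.75), Ly86 (-1.65), Csf1r (-1.16) and Cd14 (-0.85) fell. The members with the brightest probe sets, Cybb, Ctss, Cd68 and Psap, had EVI1 means of 12.26, 12.92, 12.75 and 12.11 against EGFP means of 12.25, 11.92, 11.58 and 11.54. Of the 25 genes 23 lay above the olfactory percentile in the EGFP arrays, and 2 are in another list. Brightness of different probe sets does not rank their transcripts by abundance. A difference between the virus preparations or their dose cannot be told apart from the construct, because each group received 1 construct and the labels give no dose; the list mean differed by 2.09, 1.40 and 2.32 between same-numbered arrays. An effect of EVI1 itself also stays open and untested.

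Members of the neutrophil and granule list went both ways, with 10 down, 5 up and bright members such as S100a8 (-0.19 ± 0.32, SE) not passing. A ceiling common to all bright probe sets is argued against, since 8 of the 165 genes at least as bright as S100a8 fell at least 2-fold. Of all genes tested, 3.03% fell as much. Those 8 include Mpo and Ctsg of this same list. A ceiling can differ between probe sets, so they do not show whether those of S100a8, Lyz2 or Chil3 were saturated. A lower share of neutrophil-lineage cells as a whole stays open: 5 members rose, but the pattern was defined by members that do not fall, and the EGFP means of Ly6g and Mmp9 lay under the olfactory percentile. An effect of EVI1 on single genes was not tested.

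Among 11799 probe sets unnamed here, 429 (3.64%) differed between the groups, 182 higher and 247 lower in the arrays labelled EVI1, with log2 fold changes from -3.50 to 3.10 (the gene comparison left these probe sets out, while the count over every probe set includes them). Among 1321 probe sets with several gene symbols, 105 (7.95%) differed, 48 higher and 57 lower, with log2 fold changes from -3.89 to 4.22 (also left out of the gene comparison). Both counts were adjusted over all 34760 probe sets. At that adjustment 2420 (11.2%) of the 21640 probe sets with 1 gene symbol differed.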

How the results depend on the processing

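The filter at the olfactory receptor level was chosen after the data were seen; the other alternatives were planned. The changed genes numbered 3446 to 4361 under the scalings, filters, variance settings, array weights, replicate block and mean over probe sets, 2954 over every probe set, and 3609 with the olfactory filter. At an adjusted p under 0.01 they were 1896 (938 up, 958 down), as the stricter threshold requires. Leaving out 1 array gave 2289 (without EVI1 replicate 3, fewer arrays) to 4098 (without EGFP replicate 2) changed genes, 1179 to 2037 up and 1110 to 2061 down, and 1008 to 1248 genes at 2-fold. In the alternatives that test these genes, 0 calls turned their sign. Mecom ranged from -0.87 (without EGFP replicate 1, adjusted p = 0.0306, the only alternative where it passed, in a range up to 0.361) to -0.30 when 1 array was left out, and from -0.60 to -0.42 otherwise, with no value under the filter at the median level, which removed it. Of 10 lists called, 8 passed under every alternative but the estimated correlation, which called 0 (lowest adjusted p 0.199). Few residual degrees of freedom and correlated members were not told apart as causes of that 0. Fry, which tests against no change, called 17 lists, with stem cell, TGF-beta, AP-1, cytokine, lymphoid, megakaryocyte and p53 gained. The erythroid and apoptosis lists lost their call as given in the report, within ranges of 0.0108 to 0.330 and 0.00528 to 0.308 of their adjusted p. For lists not called that camera called under an alternative, its adjusted p ranged from 0.0105 to 0.509 (neutrophil), 0.0271 to 0.385 (dendritic), 0.0127 to 0.375 (p53), 0.0259 to 0.385 (eosinophil) and 0.0470 to 0.385 (megakaryocyte). Test directions turned only in lists not called, and the cause was not tested: lymphoid (0.32 with the filter at the median level), monocyte (-0.17 to 0.027 leaving out 1 array, the last without EGFP replicate 1), stromal (-0.045 to 0.051 leaving out 1 array, with the direction turned at -0.011 without EGFP replicate 1, and at 0.031 on ranks) and adhesion (-0.18 to -0.0049 leaving out 1 array, the test direction turned at -0.12 without EGFP replicate 2). Of 1534 values of 110 named genes under alternatives, 1511 kept direction and call, 16 lost and 7 gained the call and 0 turned; 12 genes account for the 23 changes. Leaving out 1 array ended the call of Ephx1 (adjusted p up to 0.0988), H2-Ab1 (0.0801), Pdgfrb (0.0726), Ebp (0.0571), Tm7sf2 (0.0610), Perp (0.0563) and Cd86 (0.0511), and gave one to Ear6 (0.0398 without EGFP replicate 2). Among the lists not called, the lymphoid, adhesion and stromal medians also changed sign (0.025 without EGFP replicate 1, 0.032 with the filter at the median level and -0.014 with array weights). The stricter dim filter took the eosinophil median to -0.83, TGF-beta to 0.38, AP-1 to 0.19 and monocyte to -0.17, while array weights took the apoptosis median to 0.33 and the stem cell median to 0.051. The replicate block moved counts of members within a list by at most 2 up and 4 down, and changed no call of lists and genes named by rule but those of the neutrophil, eosinophil, dendritic and p53 lists and of Epx, Prg2, Prg3 and Pecam1 (-0.44, 0.0251). Scalings moved the median of all genes by less than 0.02. Signal over background could not be judged, and of the largest changes 6 rises and 4 falls have one group under the olfactory level, so their folds are uncertain.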

Other observations

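All 14 gene families of this part and the members named from them were chosen, and the tests run, after the values had been seen. Camera p-values were adjusted over the 14, which does not correct for that choice. The p-values therefore describe the families and do not test them. Mitochondrial ribosomal proteins and aminoacyl-tRNA synthetases were lower in the arrays labelled EVI1, while cytosolic ribosomal proteins were not called. Of 74 mitochondrial ribosomal proteins 21 fell and 1 rose, with a median log2 fold change of -0.30 (camera adjusted p = 4.78e-07, adjusted p = 0.144 with an estimated correlation). Of 30 aminoacyl-tRNA synthetases, which load amino acids onto transfer RNAs, 11 fell and none rose (1 rose after a further quantile normalisation), with a median of -0.26 (camera adjusted p = 2.49e-05, adjusted p = 0.134 with an estimated correlation); Tars fell by 1.37 ± 0.14 (SE), Hars by 0.98 ± 0.13 and Lars by 0.99 ± 0.14. Of 9 chaperonin subunits 4 fell and 1 rose (median -0.37, adjusted p = 0.00736, adjusted p = 0.199 with an estimated correlation). The 57 cytosolic ribosomal proteins had a median of 0.027 (-0.0064 after a further quantile normalisation), and 1 of them, Rpl12, fell (2 fell after that normalisation; adjusted p of the family 0.917). Of 39 proteasome subunits 5 fell (3 after centring, 6 after a further quantile normalisation) and 2 rose (median -0.068, adjusted p = 0.163). Of 23 killer cell lectin-like receptors 5 fell (4 after either scaling) and none rose, with a median of -0.21 (adjusted p = 0.00197, adjusted p = 0.134 with an estimated correlation).

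Higher families included guanylate-binding proteins, cathepsins and metallothioneins, and each of their calls was lost with an estimated correlation. Of 8 guanylate-binding proteins, interferon-induced GTPases, 7 rose with a median of 2.27 (camera adjusted p = 4.78e-07, adjusted p = 0.134 with an estimated correlation), among them Gbp5 (3.04 ± 0.24) and Gbp11 (2.75 ± 0.34). All 6 genes of the Trim12, Trim30 and Trim34 group rose, with a median of 1.79 (adjusted p = 2.26e-06, adjusted p = 0.134 with an estimated correlation). The guanylate-binding protein gene Gbp3 and Trim30a are also in the interferon list, so these families are not separate from that result. Of 17 cathepsins 11 rose, with Ctsl at 2.33 ± 0.25 and Ctso at 1.81 ± 0.17, and Ctsg fell; the median was 0.72 (adjusted p = 1.73e-06, adjusted p = 0.134 with an estimated correlation). In the placental cathepsin cluster 4 of 6 rose, Ctsj, Ctsr, Cts6 (1.71 ± 0.13) and Cts8 (0.39 ± 0.10), with a median of 1.05 (adjusted p = 0.000779, adjusted p = 0.134 with an estimated correlation), and hybridisation between these paralogs was not tested. Of 21 subunits of the vacuolar ATPase, which acidifies lysosomes, 5 rose (4 after centring) and none fell, with a median of 0.22 (adjusted p = 0.00331, adjusted p = 0.134 with an estimated correlation). Of 4 metallothioneins, which bind metals, Mt2 (3.78 ± 0.28) and Mt1 (0.85 ± 0.12) rose (adjusted p = 0.00512, adjusted p = 0.134 with an estimated correlation). Of 21 aldehyde dehydrogenases 7 rose and 2 fell, with Aldh1a1 at 2.13 ± 0.12 (adjusted p = 0.0200, adjusted p = 0.134 with an estimated correlation), and of 20 glutathione S-transferases 5 rose and 1 fell (adjusted p = 0.0791). Some single genes were picked by no rule, after their values had been seen, from the 573 that rose at least 2-fold. They were the oxidative stress genes Nqo1 (3.13 ± 0.17) and Hmox1 (2.11 ± 0.28), Akr1b8 (3.65 ± 0.18), the epithelial genes Epcam (3.19 ± 0.21) and Muc1 (3.63 ± 0.23), fibronectin (Fn1, 3.25 ± 0.16) and the embryonic globin Hbb-y (2.76 ± 0.18, from 6.12 to 8.87). No list of oxidative stress or epithelial genes was tested. The EGFP means of Gbp5, Gbp11, Ctsj, Ctsr, Cts6, Cts8, Akr1b8, Epcam, Muc1 and Hbb-y lay under the 95th percentile of olfactory receptor genes, so their folds are uncertain.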
